A study of Arabidopsis thaliana with 12 samples.

How the data were processed

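Total RNA of *Arabidopsis thaliana* was measured on 12 expression arrays, 6 of the wild type (WT, ecotype Columbia 0) and 6 of the *stn8* mutant. The groups were taken from the sample titles, since the source field describes all 12 samples as WT. The titles number the samples 1 to 6 within each group. Nothing in the labels says that the numbered samples came from separate plants, so p-values measure only the spread between these arrays, which may be technical. The tissue, growth conditions, array design and scanner were not given in the sources used here.

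The deposited intensity values were on a linear scale, as read from the values themselves, with no value below 0. How the authors corrected the background and scaled the arrays was not given in the sources used here. Array means lay between 1.05 and 1.14 and were not equal, and what the values are relative to stays unknown. Between 173 and 254 probes per array were listed at exactly 0, and no rule for these zeros was found in the labels. For arrays the number of arrays limits the precision. All value columns were used.

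The value table had 3439 rows, of which 2 held no value and were left out, leaving 3437 probes. The platform annotation named 1 gene for 692 probes and several genes for 869, and it did not list 1876 probes, which are unnamed here. Gene identifiers were updated through the TAIR10.1 gene table, which matched 690 of the 692 probes. Genes were named only from probes with 1 gene. The layout of spots on the array was not given, so positions are described by the spot number of each probe.

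Zeros were set to the smallest positive value of their array and intensities were converted to log2. The array medians then differed by 0.311 on the log2 scale, above the limit of 0.1 set before the data were examined, and the arrays were quantile normalized. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 6 arrays against 6), with Benjamini-Hochberg adjustment over 3437 probes and an adjusted p threshold of 0.05. Fold changes are stn8 minus WT on the log2 scale with the standard error of the fit, and means of intensity are given with the SD over 6 arrays. Where a gene is said to change N-fold, the number is the ratio of the means of its deposited intensities, and it differs from the fitted log2 fold change, which is of quantile-normalized values. Counts of probes past a minimum fold and the ranking of genes use the fitted value. For dim probes the normalization and the treatment of low values can move the fold, so for called genes with a mean intensity under 0.1 in a group the log2 fold change without normalization and after adding a pseudocount of 0.0585, the 5th percentile of positive values, is given as well. No fold is given against a group listed at 0 on all its arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

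Gene lists were fixed before the data were examined, 17 lists with 291 loci. Lists with at least 3 measured members were tested with camera (preset correlation 0.01, and with an estimated correlation) and with fry, which asks whether members move 1 way on balance and does not compare them with other genes. The rule for named genes, also fixed before, took the 12 largest rises and the 12 largest falls among called genes whose 6 stn8 values lay on 1 side of the WT mean, up to 4 called members of each list (or 2 where none was called), and the list of STN8, STN7 and related kinases and phosphatases, none of which had a probe of its own here. The rule did not mention zeros. The ranking was limited to probes above 0 on all 12 arrays, since values at the floor have no order, and this limit was added after the data were seen. It did not exclude *AT3G08000*, whose value on WT array 5 was above 0 but at that floor.

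Samples with the same number deviated together from their group means, with correlations from 0.12 to 0.16 in all 6 pairs, above the limit of 0.1 set for pairing. Arrays of different number were not compared in this way across the groups, so these values do not show that the number itself matters. The numbers come from the titles and their meaning is not stated there. The fit was tested on simulated data with the spread of the 3079 probes above 0 on all arrays. It recovered 61.2% of changes of 0.5 on the log2 scale, 94% of changes of 1 and 97% of changes of 2, and 4.55% of its calls were unchanged probes. Of simulated lists with no shift, 4% had a camera p under 0.05. The simulated arrays varied independently, only a small share of probes was changed, and no normalization was applied. In the data most probes were called and neighbouring arrays resembled each other, so these shares do not give the error rates of the real comparison.

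The alternatives tried were no normalization between arrays, median centring, cyclic loess, removal of the dimmest 33.3% of probes, the pseudocount, an intensity trend with robust variances, array weights, the sample number as a replicate block, leaving out each array in turn, a minimum fold of 1.5, and the other set tests. Alternatives chosen after the data were seen were averaging arrays 1 and 2, 3 and 4, and 5 and 6 of each group, with and without a block, the same pairs as a random block, leaving out probes at 0 on any array, leaving out WT arrays 5 and 6, counting shared probes on the lists, and pooling the 5 photosynthesis lists. Genomic coordinates are not given because the build behind the array design was not given in the sources used here.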

Results

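Transcript levels were measured with 12 expression arrays of *Arabidopsis thaliana* total RNA, 6 from the WT and 6 from the *stn8* mutant, with 3437 probes each. STN8 is a protein kinase of the thylakoid membrane that phosphorylates core proteins of photosystem II. The comparison asks which transcripts differ in level between the mutant and the WT. The median intensity per array lay between 0.297 and 0.369 in WT and between 0.331 and 0.349 in stn8. The highest intensity on an array was 166 to 193 in WT and 84.4 to 93.9 in stn8, and 173 to 190 probes were at 0 on a WT array against 220 to 254 on a stn8 array. STN8 and STN7 had no probe of their own in the annotation used, so the mutation could not be checked from the level of its gene.

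Most probes differed between the groups. Of 3437 probes, 2421 (70.4%) passed the limma test, 1191 higher and 1230 lower in stn8, and 1232 of them changed at least 2-fold in the fit. At an unadjusted p under 0.05 the count was 2486. The 6 values of one group did not overlap the 6 of the other for 1912 probes (55.6%), where chance gives 0.217% if all 12 arrays are exchangeable, 3.13% if only arrays of the same number are and 10% if neighbouring arrays of a group go together. Among the 692 probes that named 1 gene, 490 were called, 278 higher and 212 lower. Over the 3079 probes above 0 on all arrays, the median absolute log2 fold change was 0.75, against a median SD of 0.24 within WT and 0.15 within stn8.

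Arrays of the same group resembled each other far more than arrays of different groups. Across the 3079 probes, Pearson's r was 0.905 to 0.969 within WT, 0.972 to 0.986 within stn8 and 0.676 to 0.725 between the groups; probes are not independent replicates. Each of the 12 arrays was closest, within its group, to its neighbour in number (1 with 2, 3 with 4, 5 with 6), and WT arrays 5 and 6 stood apart from WT arrays 1 to 4, with r of 0.905 to 0.921 against at least 0.952 among the latter. With such neighbours averaged, so that each group had 3 values, 2011 probes were called, of which 2000 were among the 2421.

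**Figure D1:**
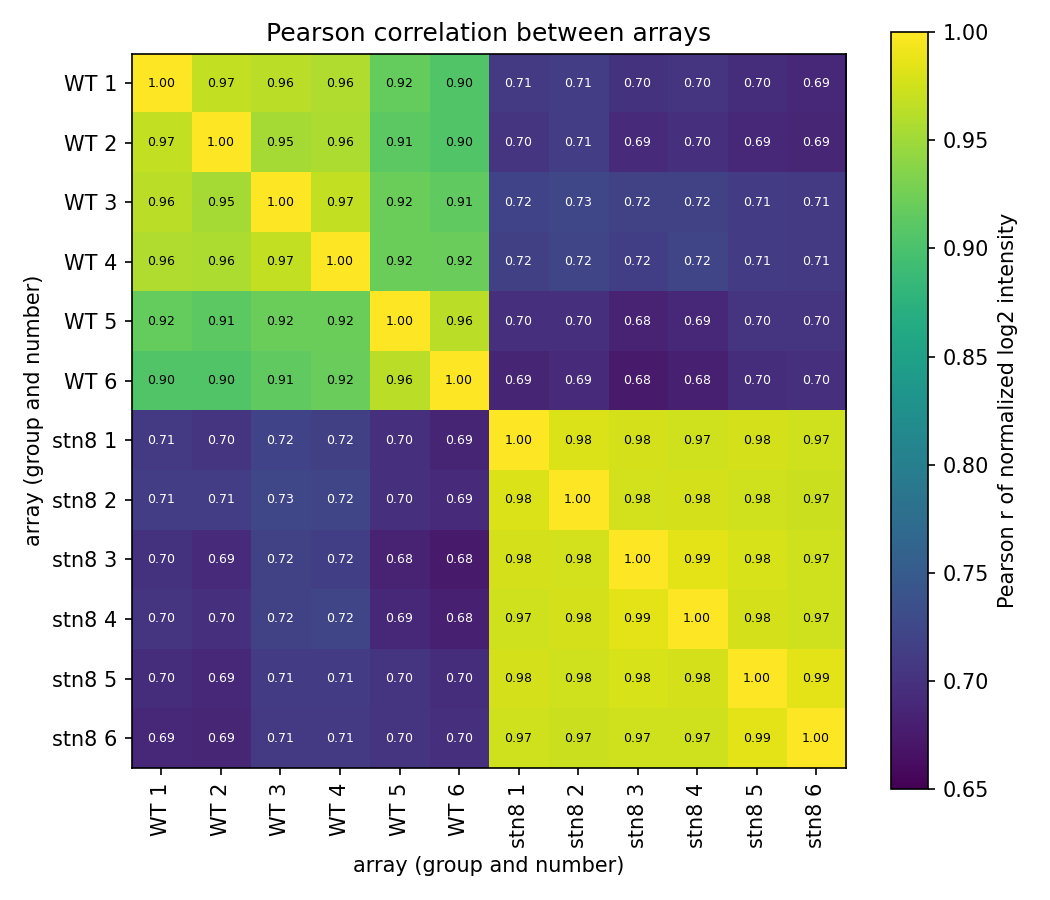
Pearson correlation of normalized log2 intensities for every pair of the 12 arrays (rows and columns, WT 1 to 6 and stn8 1 to 6), over the 3079 probes above 0 on all arrays. Pairs within a group lie between 0.905 and 0.986 and pairs across groups between 0.676 and 0.725.

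Of 7 probes on the photosynthesis lists, 6 were called lower in stn8. Folds given here are ratios of deposited means, and log2 fold changes are those of the fit on normalized values. *PSAN*, a lumenal subunit of photosystem I, fell from an intensity of 4.68 ± 0.955 (SD, n = 6) to 0.517 ± 0.0385, which was 9.05-fold, with a log2 fold change of -3.42 ± 0.13 (SE, adjusted p = 7.83e-10), and its fitted fall was the largest among the genes ranked. *LHCB1.5*, a chlorophyll-binding antenna protein of photosystem II, fell 6.23-fold, from 8.80 ± 0.838 to 1.41 ± 0.0839 (log2 fold change -2.99 ± 0.07, adjusted p = 1.33e-11). *PSBW*, a small subunit of photosystem II, fell 5.85-fold, from 44.0 ± 5.48 to 7.53 ± 1.16 (-2.71 ± 0.10, adjusted p = 4.75e-10). *PRK*, the Calvin cycle enzyme phosphoribulokinase, fell 3.92-fold, from 1.29 ± 0.239 to 0.330 ± 0.0434. *PSB27*, a photosystem II assembly factor, fell 1.97-fold, from 2.00 ± 0.405 to 1.02 ± 0.191. Spots above an intensity of 10 in stn8 lay within 4 spot numbers of *PSAN*, *LHCB1.5* and *PSBW*, and whether the *LHCB1.5* probe tells the near-identical LHCB1 copies apart was not given in the sources used here.

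Of the photosystem II list, 3 of 15 genes had a probe of their own, and all 3 were called lower, both over all probes and adjusted over the list alone. The smallest of these changes was that of *PSBY* (-0.31 ± 0.09, adjusted p = 0.0122), whose mean intensity was 1.78 ± 0.253 in WT and 1.74 ± 0.164 in stn8. Its call was lost without normalization (log2 fold change -0.02) and with median centring (-0.08), and also with array pairs as a random block (adjusted p = 0.127) and with averaged pairs and a block (adjusted p = 0.0546). The list had a median log2 fold change of -1.23 and did not pass camera (adjusted p = 0.0884, and adjusted p = 0.148 with an estimated correlation). The photosystem I and light-harvesting lists each had 1 probe, *PSAN* and *LHCB1.5*, called also when adjusted over the list alone. Of the 2 Calvin cycle probes *PRK* was called, over all probes and adjusted over the list alone (1 gene). *SBPASE*, sedoheptulose bisphosphatase, had 0.668 ± 0.197 in WT and 0.242 ± 0.160 in stn8, with stn8 array 5 at 0 (adjusted p = 0.132), and without that array it was called lower (log2 fold change -1.38, adjusted p = 0.00757). The electron transport list had no probe of its own. Pooling these 5 lists, chosen after the values were seen, gave 7 probes, 6 of them called lower (6 also adjusted over the list alone), with a median of -2.71 (camera p = 0.00102, and p = 0.0143 with an estimated correlation). That median was -1.92 with the pseudocount, which lessens the weight of the 0 in *SBPASE*.

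**Figure D2:**
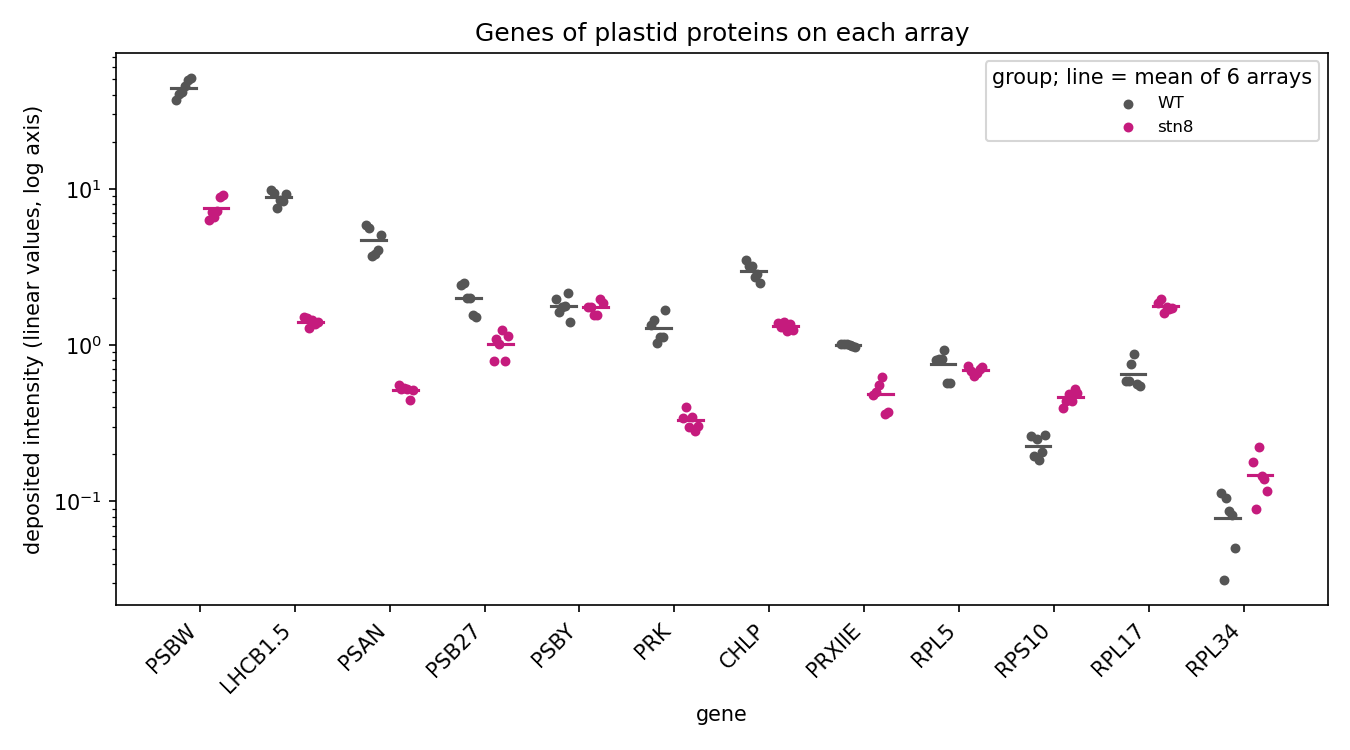
Deposited intensity (log axis) of 12 genes of plastid proteins on each array, WT in grey and stn8 in magenta, with a line at the mean of 6 arrays. For *PSAN* the WT mean is 4.68 and the stn8 mean 0.517, while for *RPL17* they are 0.654 and 1.78 and for *PSBY* 1.78 and 1.74.

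Plastid ribosomal protein genes went both ways. Of 39 listed genes 6 had a probe of their own, of which 3 rose, 1 fell and 2 were not called, and 4 passed when adjusted over the list alone. *RPL17* rose 2.72-fold, from 0.654 ± 0.132 to 1.78 ± 0.13 (1.21 ± 0.10 on the log2 scale, adjusted p = 6.64e-07), and *RPS10* 2.04-fold, from 0.228 ± 0.0359 to 0.464 ± 0.0464. *RPL34* rose from 0.0782 ± 0.0316 to 0.149 ± 0.0467 (1.69 ± 0.46, 0.995 without normalization and 0.89 with the pseudocount), and its call was lost with array pairs as a random block (adjusted p = 0.111). *RPL5* fell slightly (-0.30 ± 0.11, adjusted p = 0.0251), and this call was lost without normalization (-0.10), with median centring (-0.15), with averaged pairs, with or without a block, and without WT array 1, 2 or 4 or stn8 array 3 (log2 fold change -0.24 to -0.28). *RPS6* was at 0.111 in WT and 0.0844 in stn8. Its log2 fold change was 0.14 in the fit, against -0.37 without normalization and 0.06 with the pseudocount, and it was not called. *RPL29* was at 0 on all 12 arrays and entered the list at a log2 fold change of 0. The list had a median of 0.58 and did not pass camera (adjusted p = 0.295, and adjusted p = 0.309 with an estimated correlation). Without probes at 0 on any array, the median of the 5 probes left was 1.015 (camera adjusted p = 0.263).

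Other plastid enzymes were represented by few probes. *CHLP*, the geranylgeranyl reductase that supplies the chlorophyll side chain, fell 2.25-fold, from 2.98 ± 0.370 to 1.33 ± 0.0719 (-1.44 ± 0.10, adjusted p = 1.11e-07). *CHLM*, a methyltransferase of chlorophyll synthesis and the other of 2 probes on the tetrapyrrole list, did not pass (0.480 in WT and 0.521 in stn8, adjusted p = 0.918). *PRXIIE*, a plastid peroxiredoxin and the only probe of the antioxidant list, fell 2.07-fold, from 1.0 ± 0.0222 to 0.484 ± 0.103 (-1.25 ± 0.12, adjusted p = 1.94e-06). *CHLP* and *PRXIIE* were the 1 call of their lists also when adjusted over the list alone. In all, 10 of the 17 lists had no probe of their own: the kinases and phosphatases, electron transport, carotenoid, starch, photorespiration, plastid proteases, protein import, plastid transcription, pathogenesis-related genes, and the markers of other tissues (seed and epidermis). Tissue composition was therefore not checked.

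Among the other large falls were *AT4G32060* (9.35 ± 1.01 to 1.2 ± 0.122, 7.83-fold), which encodes a calcium-binding regulator of the mitochondrial calcium uniporter, and *AT1G62250* (8.05 ± 0.768 to 1.09 ± 0.0571, 7.39-fold). *XERICO*, a RING-type protein tied to abscisic acid and drought, fell 4.79-fold, from 5.97 ± 0.581 to 1.25 ± 0.0446 (-2.54 ± 0.06, adjusted p = 7.53e-12). *CUTA*, a copper-binding plastid protein, fell 4.34-fold, from 5.31 ± 0.257 to 1.23 ± 0.0484. The remaining falls of this group were *AT2G40980* (7.74-fold), *AT4G31470* (4.85-fold) and those of 3 genes that were dim in stn8. For *AT4G39570* (0.545 to 0.0675) the log2 fold change was -2.86, against -3.12 without normalization and -2.18 with the pseudocount, for *AT4G00170* (0.609 to 0.0808) -2.77, against -2.94 and -2.19, and for *AT2G06040* (0.555 to 0.0963) -2.48, against -2.73 and -1.86. The *AT2G40980* probe lay within 4 spot numbers of a spot at 39.8 in stn8. As near to *AT2G06040* lay a spot at 9.35 in stn8 and 0.432 in WT, and to *XERICO* one at 6.92 and 0.894. *AT4G39570*, in contrast, fell beside a spot at 13.1 in WT and 2.24 in stn8. *AT2G06040* lost its call with averaged pairs and a block (adjusted p = 0.0572). Its deposited intensities overlapped between the groups, with WT arrays 5 and 6 at 0.224 and 0.212 and stn8 array 5 at 0.235.

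Among the genes ranked, all from probes above 0 on all arrays, the largest rise was that of *AT3G12000*, which encodes an S-locus-related protein, from 1.38 ± 0.377 to 39.8 ± 1.64, 28.7-fold (4.77 ± 0.17, adjusted p = 4.58e-10). *AT2G18920* rose 28.2-fold, from 0.298 ± 0.0354 to 8.42 ± 0.682, *AT1G02260* 18.7-fold, from 0.688 ± 0.0517 to 12.9 ± 0.839, and *AT4G09620* 13.1-fold, from 3.65 ± 0.85 to 47.9 ± 4.82. *AT2G31800* rose 15.3-fold. Spots above 10 in WT lay within 4 spot numbers of *AT2G18920* (25.7 in WT and 3.45 in stn8) and of *AT2G31800* (13.0 in WT and 1.54 in stn8). *AT4G09620*, in contrast, rose as near to a spot at 12.96 in stn8 and 5.36 in WT. *AT5G06990* rose from 0.363 ± 0.0316 to 5.09 ± 0.337 and *AT3G04650* rose 9.71-fold. *AT3G52550* rose from 0.0815 ± 0.0581 to 0.472 ± 0.0292 (3.75 ± 0.77, 2.86 without normalization, 2.18 with the pseudocount and 3.12 without WT array 5). The other 4 of the 12 rises also came from dim probes, and their fitted log2 fold changes shrank without normalization and with the pseudocount. By deposited means they rose only 1.76-fold (*AT3G08000*), 2.03-fold (*AT2G24810*), 1.65-fold (*AT3G53580*) and 1.89-fold (*AT3G61680*). For *AT3G08000* it was 4.21, against 2.18 without normalization and 0.74 with the pseudocount, and for *AT2G24810* 3.62, against 1.3 and 0.93. *AT3G08000* had on WT array 5 the smallest positive value of that array, the one given to zeros, and its log2 fold change was 3.28 without WT array 5 and 4.88 without WT array 3. That of *AT2G24810* was 4.23 without WT array 4. For *AT3G53580* it was 3.28, against 0.69 and 0.77, and for *AT3G61680* 3.27, against 0.93 and 0.80. *AT3G08000* and *AT3G61680* lost their calls without normalization and with median centring, *AT2G24810* and *AT3G61680* with averaged pairs, and *AT2G24810*, *AT3G08000* and *AT3G52550* with averaged pairs and a block.

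**Figure D3:**
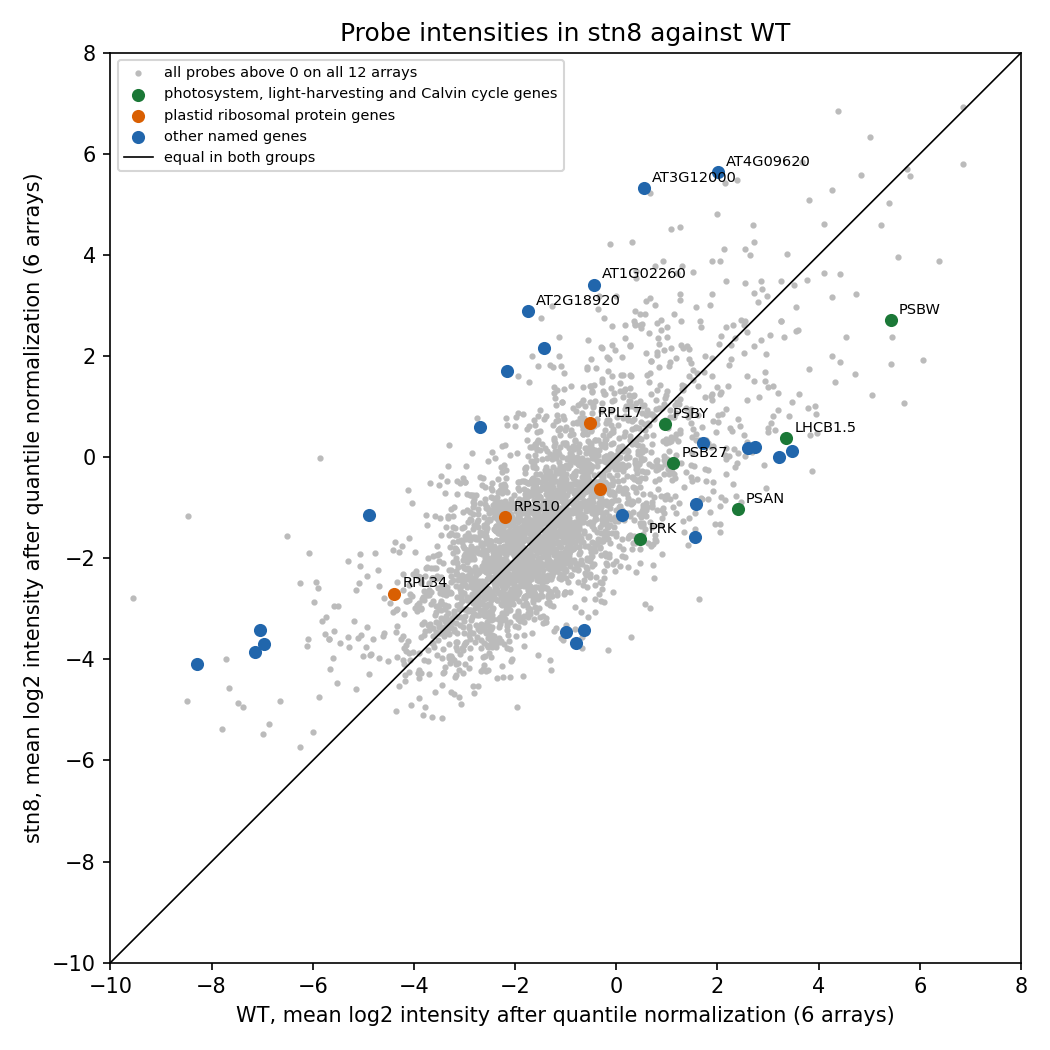
Mean log2 intensity after quantile normalization in stn8 (vertical axis) against WT (horizontal axis), 6 arrays each; grey points are the 3079 probes above 0 on all arrays, coloured points the named genes, and the line marks equal levels. *PSAN*, *LHCB1.5* and *PSBW* lie below the line, at log2 differences of -3.42, -2.99 and -2.71, and *AT3G12000* lies above it, at 4.77.

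Some probes were at 0 in a whole group. There were 54 probes at 0 on all stn8 arrays but not on all WT arrays, 28 the other way round, and 100 at 0 on all 12 arrays. Among probes with 1 gene, 9 such probes were called, and they are named here after their values were seen. Listed at 0 in stn8 were *AT2G47360* (1.46 ± 0.564 in WT), *AT2G03200* (0.50 ± 0.0944), *Z-ISO*, an isomerase of carotenoid synthesis (0.190 ± 0.0366), and *GLX2-1*, a glyoxalase-like protein (0.121 ± 0.0238). So were 3 genes dim in WT, *AT4G37420* (0.063 ± 0.046), *AT3G11960* (0.046 ± 0.023) and *AILP1* (0.016 ± 0.011). Listed at 0 in WT were *AT2G11270* (3.75 ± 0.409 in stn8) and *AT4G22830*. The latter was near 0 in stn8 as well (0.0297 ± 0.0336), with 2 stn8 arrays also at 0. *AT2G11270* had no spot above 10 within 4 spot numbers in either group (brightest neighbour at 0.521 in WT and 1.79 in stn8). Of the 7 at 0 in stn8, 6 (all but *AILP1*) lay within 4 spot numbers of a spot above 10 in stn8. Of these 6, 4 also lay that near a spot above 10 in WT, where they were above 0 on all 6 arrays, namely *AT2G03200* and *AT4G37420* (neighbour at 18.7 in WT and 83.5 in stn8) and *Z-ISO* and *GLX2-1* (10.6 and 51.9).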

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

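Tests chosen after the result was seen were those of normalization, of values near 0 and of shared plants, RNA or hybridization, those of bright neighbours and of clock genes for the photosynthesis probes, and the count of probes at 0 beside bright spots, and so was the pooling of the photosynthesis lists. An array far from the others was looked for in 70 groups of 6 values, and 0 stood out. These were the values of the 33 genes named by the rule and the array medians and counts of zeros, within each group. *SBPASE* and *SRX*, each with a stn8 array at 0, were not among the genes tested.

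For the 2421 called probes, splits argue against chance only if single arrays can be exchanged. Of 100 splits of the 12 arrays, 1, the real one, gave as many (highest other 1). So did 1 of the 32 splits that part every same-numbered pair (highest other 1). Such splits do not keep neighbouring arrays together. With the arrays averaged in pairs (2011 called, highest other 0) the 10 splits are too few for a share under 0.05. Chance is therefore not excluded if neighbouring arrays are repeats. Array scale is argued against as the whole cause by the 2460 probes called with median centring and the 2422 with cyclic loess. The 2414 called without normalization bear on the normalization as a cause, but not on array scale, which is left in place there. Values near 0 are argued against as the whole cause by the 83.8% called among 1146 probes in the brightest 33.3% and above 0 on all arrays. Local background beside bright spots is also argued against as the whole cause by the 69.0% called among 2286 probes with no spot above 5 within 6 spot numbers. Plants, RNA or hybridization shared by all arrays of a group cannot be told apart from the genotype, because the labels gave 0 batch characteristics. A wrong group label stays open too, since no probe of STN8 was used and the source field gives WT for all samples, and so does a real effect of the mutation, which was not tested separately.

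Of the 7 photosynthesis probes, 6 were called lower, with a median log2 fold change of -2.71. Compression that follows the mean intensity is argued against by the place of this median, at percentile 0.01 of 10000 random lists. Of these lists, matched on the mean normalized intensity over all arrays, 95% had medians from -1.15 to 1.32. Probes matched in this way need not be as bright in WT as *PSBW*. Compression of the probes brightest in WT was therefore not tested. Background correction beside bright spots could lower *PSAN*, *LHCB1.5* and *PSBW*, and it stays open for the set. The 4 probes away from such spots had a median of -1.67, at percentile 0.58 of their matched lists. One of them, *SBPASE*, has an array at 0 and lay within 4 spot numbers of a spot at 7.78 in stn8 and 0.359 in WT, below the limit of 10. Without *SBPASE* the 3 left had -1.23, at percentile 5.27. Harvest at another time of day or light state cannot be told apart from the genotype, because 1 of 21 clock and light genes listed had a probe of its own, *CCL*, at -2.06. A lower level of photosynthesis transcripts in the mutant stays a hypothesis.

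Of the 25 probes at 0 on all stn8 arrays and on no WT array, 21 lay within 4 spot numbers of a spot above 10 in stn8, against a mean of 2.44 over 1000 rotations of the spot numbers, none of which reached 21 (highest 15). Of the 6 probes at 0 on all WT arrays and on no stn8 array, 5 lay within 4 numbers of a spot above 10 in WT (1 of 1000 rotations had as many). The other was *AT2G11270*, with no spot above 10 that near in either group. But 8 of the 21 also lay that near a spot above 10 in WT, as did all 5 in stn8, without being at 0 there. Background correction beside bright spots is a candidate explanation for the zeros that lay beside such spots, though a neighbour above 10 was not enough for a 0. It was not borne out for dim neighbours of spots brighter in WT, whose median log2 fold change was 0.056 (136 of 1000 rotations had a median as high). Dim neighbours of spots brighter in stn8 had -0.45 (0 of 1000 as low). The 4 numbers and the intensity of 10 were set after the zeros had been inspected, spot numbers may not follow the layout of the array, and a real loss of *Z-ISO*, *GLX2-1* and the others in stn8 stays open and was not tested.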

How the results depend on the processing

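Alternatives chosen after the data were seen were averaged pairs, pairs as a random block, leaving out probes at 0, leaving out WT arrays 5 and 6, shared probes and the pooled list. Of 29 alternatives 25 gave values for named genes, with 25 of the 33 genes measured in each of them. Directions of named genes and list medians remained wherever a value was had, and 25 genes kept their call wherever they had a value. The count of called probes (2421) was 2414 without normalization (2205 shared with the 2421), 2460 with median centring, 2422 with cyclic loess, 2455 with the pseudocount, 2434 with trend and robust variances, 2505 with array weights, 1841 of 2291 without the dimmest 33.3%, 1845 at 1.5-fold or more, and 2341 to 2421 with each array left out in turn. It was 2011 with averaged pairs, 2015 with averaged pairs and a block, 2150 with pairs as a random block, 2328 of 3079 without probes at 0, and 2493 without WT arrays 5 and 6. With the sample number as a replicate block it was 2477, and that block changed no call of a named gene or list. The photosystem II list (median -1.23) and the plastid ribosomal list (0.58) passed only with fry (adjusted p = 2.04e-09 and 4.72e-07, over camera's 0.0724 to 0.221 and 0.217 to 0.359 in the other alternatives); fry compares no list with other genes, by its construction. The median of the pooled list was -2.06 without stn8 array 5 and -2.10 with shared probes. Over all 3437 probes, those at 0 included, no 2 arrays of a group had deviations correlated over 0.5 (highest 0.376). The planned averaging of such arrays therefore gave no value. These correlations were not computed over the 3079 probes above 0 on all arrays. The limit therefore does not settle whether neighbouring arrays are technical repeats. The planned STN8 level gave no value either, for lack of a probe. Probes at 0 or near it have signal too low over background for a reliable fold.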

Other observations

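Genes in this part were chosen after their values were seen. Folds are ratios of deposited means. Subunits of and factors for the chloroplast NDH complex, which carries cyclic electron flow around photosystem I, went both ways. *NdhS* rose 4.47-fold, from 18.7 ± 2.18 to 83.5 ± 3.62 (2.47 ± 0.06 on the log2 scale, adjusted p = 1.08e-11), and *CRR41* 1.92-fold, from 0.492 to 0.945. *NdhN* fell 2.09-fold, from 0.396 to 0.189. *CRR21* (adjusted p = 0.0721, and 0.0428 without WT array 3) and *PIFI* (adjusted p = 0.375) were not called, with log2 fold changes of -0.18 and -0.07. The plastid chaperonin genes *Cpn60beta3* and *Cpn60beta4* rose 4.03-fold and 2.36-fold. *NTRC*, a plastid thioredoxin reductase, fell from 0.381 to 0.0983 (log2 fold change -1.80, against -1.97 without normalization and -1.38 with the pseudocount), but its spot lay within 4 numbers of a spot at 51.9 in stn8 and 10.6 in WT. *SRX*, the plastid sulfiredoxin, was at 0.172 in WT and 0.0359 in stn8, with stn8 array 1 at 0 (log2 fold change -3.11, adjusted p = 0.0672). It was called without that array (-1.68, adjusted p = 0.000578) and without stn8 array 2 (-3.61, adjusted p = 0.047). Its spot lay within 4 numbers of a spot at 11.9 in WT and 3.76 in stn8.

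Outside the plastid, the glycosyl hydrolase genes *GH9B11* and *GH9B16* fell 2.19-fold and 1.62-fold. *GH9B8* was called higher (log2 fold change 0.485, limma adjusted p = 0.0147), but only 0.22 without normalization. Its deposited means differed 1.13-fold, less than their spread (0.138 ± 0.041 in WT and 0.156 ± 0.018 in stn8). *GH9B12* fell from 0.140 to 0.0382, below the pseudocount, and its log2 fold change was -1.24, against -1.9 without normalization and -0.69 with the pseudocount. Whether the probes tell these related genes apart was not given in the sources used here. Of the calmodulin-like genes *CML41* rose 3.27-fold, from 0.462 to 1.51, and *CML30* fell 2.93-fold, from 1.84 to 0.629, with its spot within 4 numbers of a spot at 39.8 in stn8.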
